A study of Mus musculus with 14 samples.

How the data were processed

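The series holds 14 libraries from mouse brain: 7 immunoprecipitated with an antibody against m6A and 7 input libraries of poly(A) RNA, from 3 sham, 2 ICH and 2 acupuncture samples. Per the labels, libraries were stranded. The authors' processing notes name fastp, HISAT2, HOMER, StringTie and edgeR without versions or roles, and the peak caller is not given in the sources used here. The notes name a human genome build, while the deposited files hold mouse Ensembl identifiers. Of 25299 genes matched by symbol to the GRCm38 annotation, 96.27% lay on the same chromosome with a start or end within 1000 bp, so coordinates are given on GRCm38.

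Gene levels were deposited as FPKM per input library, computed by the authors and named so per the file headers, for 31507 genes, of which 825 were listed at 0 in all 7 libraries. The table used here has no IP columns, so the IP-to-input test per gene that had been planned was not run. The FPKM table also held 2 columns whose headings match no sample, which were not used here. The sources used here do not say whether the samples behind them entered the peak lists and differential tables. Sham and acupuncture samples were matched to the columns headed control and EA by elimination. The peak lists give, per peak, the log2 of IP over input computed by the authors for a whole group. The differential tables give the authors' log2 IP over input in each of 2 groups and their difference. In both kinds of file the p-value and adjusted p-value are the authors' own, and only peaks with a p under 0.05, or with no p in the differential tables, are listed.

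Genes with a mean of at least 1 FPKM over the 7 input libraries were tested on log2(FPKM + 1), with a pseudocount of 1. One linear model with a mean per group was fitted in limma 3.58.1 (R 4.3.3) with a moderated variance and a mean-variance trend. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, two-sided. A further fit joined ICH and acupuncture as 1 group of 4 libraries against sham. Gene lists, thresholds, comparisons and most alternatives were chosen before the data were examined. Of 37 fixed gene lists, 34 had at least 5 tested genes and were tested with camera (limma) at a preset correlation of 0.01, with an estimated correlation and with fry beside it. The lists of neutrophils, of T and B lymphocytes and of sex-linked genes were too small (4, 1 and 4 tested genes).

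Genes named in the report follow a fixed rule. Per comparison it takes the 12 largest log2 fold changes in each direction among called genes with an approved symbol and groups that did not overlap. Where fewer passed, it adds up to 6 per direction with the smallest p, given as values. It also takes up to 4 members per list with the smallest p, all m6A genes, and the 6 largest differences per direction in each differential table.

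Peaks were counted overlapping when they shared at least 1 bp on the same strand. Covariances and overlaps between comparisons that share libraries were set beside simulated values. FPKM gives no read counts, so depth per library and the precision it gives are unknown. The pipeline was tested on simulated data with 200 changed genes of 13666. In acupuncture against ICH it called 62% of genes changed by 1 on the log2 scale and 91.5% of those changed by 2, and in ICH against sham 69% and 92.5%. In acupuncture against sham the shares were 71% and 92%, and for both haemorrhage groups 82% and 97%. Simulated genes varied independently, with the same spread in all libraries. The real ICH libraries differed by a median of 0.266 on the log2 scale, beside 0.126 for acupuncture. The shares for comparisons with ICH may therefore be too high. Alternatives changed the pseudocount, filter, normalization, variance model, replicate block, fit, fold minimum, peak thresholds and overlap, and left out each library. Removal of the trend with gene span, the overlap of peaks spanning at most 1000 bp and the alternatives of the direction count were chosen after the data were seen. Intervals and tables were computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures with matplotlib 3.10.9.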

Results

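Brain tissue of mice was profiled by m6A sequencing, in which RNA fragments carrying N6-methyladenosine are pulled down with an antibody (IP) and sequenced beside the unselected poly(A) RNA (input). The 14 libraries came from sham-operated mice (3 IP and 3 input), mice with an intracerebral haemorrhage (ICH; 2 IP and 2 input) and mice with a haemorrhage that received acupuncture at the GV20 point for 7 days (2 IP and 2 input). The deposited values were FPKM per gene for the input libraries, 1 peak list per group and 1 table of differential peaks per pair of groups. Read depth per library was unknown, because only FPKM was given, whose total ranged from 179810 in ICH replicate 2 to 198472 in acupuncture replicate 1. The number of genes with a value above 0 was 23495 in ICH replicate 2 and ranged from 24028 to 24746 in the other libraries. The labels did not say that replicates were separate animals, so every p-value measures the spread between these samples. The sham and acupuncture columns carried other headings (control and EA) and were matched to the labels by elimination.

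Across the 13666 tested genes, log2 values of the 3 sham libraries correlated at 0.984 to 0.988 (Pearson's r across genes, which are not independent replicates). The 2 acupuncture libraries correlated at 0.976. The 2 ICH libraries correlated at 0.942, less than ICH replicate 1 did with acupuncture replicate 1 (0.975). ICH replicate 2 lay at -45.22 on the second principal component, while the other libraries lay between 0.98 and 18.35.

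The first comparison, ICH against sham, asked what the haemorrhage did to the tissue. Hmox1, the enzyme that degrades haem (ENSMUSG00000005413; GRCm38 chromosome 8, 75093621 to 75100589), rose from 2.29 ± 0.337 FPKM in sham (SD, n = 3) to 142 ± 2.13 FPKM in ICH (SD, n = 2). Its log2 fold change was 5.45 (SE 0.11, limma adjusted p = 6.01e-06). Serpina3n, a protease inhibitor of reactive astrocytes (ENSMUSG00000021091; chromosome 12, 104406729 to 104414329), rose from 4.38 ± 0.605 to 131 ± 4.22 FPKM, a log2 fold change of 4.63 (SE 0.12, limma adjusted p = 1.64e-05). Gfap, the astrocyte intermediate filament (ENSMUSG00000020932; chromosome 11, 102887336 to 102900912), rose from 26.2 ± 2.79 to 366 ± 39.6 FPKM. Lcn2, an iron-siderophore binding protein (ENSMUSG00000026822; chromosome 2, 32384633 to 32388252), rose from 0.645 ± 0.105 to 40.2 ± 2.34 FPKM.

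The other strongest increases were Timp1 (log2 fold change 4.49), Tgm1 (4.21), Lyz2 (4.06), Ifi30 (3.82), Ccl12 (3.73), Cd52 (3.61), C3 (3.53) and Vim (3.48). Penk, the enkephalin precursor of striatal neurons (ENSMUSG00000045573; chromosome 4, 4133531 to 4138819), fell from 178 ± 6.99 FPKM in sham to 81.0 ± 2.504 FPKM in ICH, a log2 fold change of -1.13 (limma adjusted p = 0.00151). Arl4d fell by 1.66 on the log2 scale, Hes5, a Notch target, by 1.38, Phospho1 by 1.28 and Tcap by 1.23. Also lower were Rps12-ps4 (-2.92), Vps25 (-1.45) and Zc3h11a (-1.17), which are uncertain because their reads may be shared with a near-identical or overlapping gene.

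**Figure D1:**
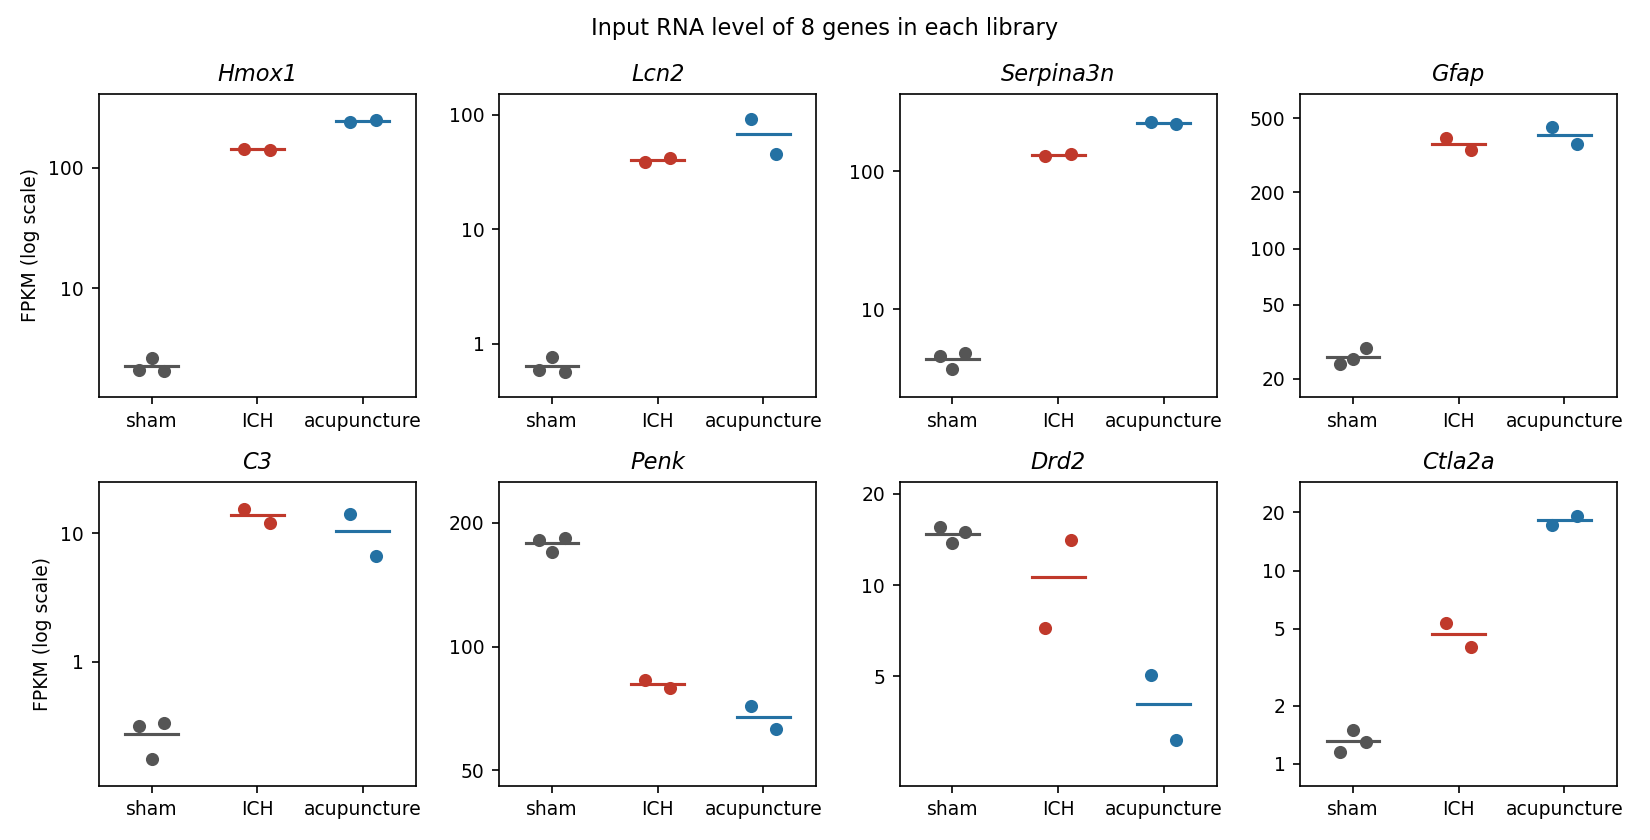
Input RNA level of 8 genes in FPKM (vertical axes, log scales that differ between panels) in each of the 7 input libraries (points) with the group mean (lines), for sham (n = 3), ICH (n = 2) and acupuncture (n = 2). Hmox1 averaged 2.29 FPKM in sham and 142 FPKM in ICH, and Penk 178 and 81.0 FPKM.

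Immune and reactive astrocyte genes rose in ICH. Of the 16 microglia and macrophage genes, 15 rose (15 adjusted over the list alone); C1qb, a chain of the first complement component, went from 21.3 ± 0.490 to 126 ± 12.7 FPKM. Of the 14 complement and antigen presentation genes, 14 rose (14 adjusted over the list alone), among them C3 from 0.274 ± 0.0853 to 13.8 ± 2.37 FPKM. Of the 15 reactive astrocyte genes, 13 rose (15 adjusted over the list alone). Of the 14 genes of lipid-laden phagocytes, 10 rose (10 adjusted over the list alone), among them Spp1, osteopontin (2.10), and Lgals3 (2.45). Of the 14 cytokine and chemokine genes, 10 rose (13 adjusted over the list alone), among them Ccl2 from 0.189 ± 0.0544 to 8.39 ± 0.794 FPKM. Of the 15 interferon response genes, 11 rose (15 adjusted over the list alone), among them Ifitm3 (2.83) and Bst2 (2.41). Of the 8 cell cycle genes, 8 rose (8 adjusted over the list alone), among them Top2a, topoisomerase II alpha, from 0.258 ± 0.0399 to 2.53 ± 0.178 FPKM.

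In haem and iron handling, 7 of 17 genes rose and 1 fell (9 and 1 adjusted over the list alone). Slc11a1, a metal transporter of phagocytes, rose from 0.419 ± 0.0731 to 4.802 ± 0.487 FPKM, and Tfrc, the transferrin receptor, fell from 16.4 ± 0.116 to 9.36 ± 0.621 FPKM. Of the 13 matrix and fibroblast genes, 6 rose (10 adjusted over the list alone), with log2 fold changes of 1.67 for Dcn and 1.60 for Fn1. Of the 15 ferroptosis and glutathione genes, 3 rose (6 adjusted over the list alone), including Slc7a11, the cystine importer (0.83). Of the 12 apoptosis and pyroptosis genes, 4 rose (5 adjusted over the list alone), including Casp8 (1.35). Of the 13 endothelial genes, 2 rose, Cdh5 (0.57) and Pecam1 (0.75), with 5 adjusted over the list alone, and neither passed when any library except ICH replicate 1 was left out.

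Striatal neuron genes fell. Of these 12, 10 fell (11 adjusted over the list alone); Syndig1l went from 17.5 ± 0.959 to 8.27 ± 0.440 FPKM. Of the 17 opioid and neuropeptide genes, 3 fell (7 adjusted over the list alone): Penk, Tac1 (-1.26) and Cartpt (-1.57). Of the 16 immediate early genes 1 fell, Egr4, and of the 5 erythroid genes 1, Hbb-bt (3 and 2 adjusted over the list alone). Egr4 did not pass without sham replicate 2 or 3, Tac1 without sham replicate 1 or 3 or ICH replicate 2, and Cartpt without any of these 3 or either acupuncture library. Hbb-bt passed without sham replicate 1 but not without any other library. Of the 11 growth factor genes, 2 rose and 1 fell (4 and 2 adjusted over the list alone), and of the 12 glucocorticoid genes 2 and 1 (3 and 2 adjusted over the list alone). Of the 12 astrocyte identity genes 1 rose, Aqp4 (1.23), which did not pass without sham replicate 1 or 2 or ICH replicate 2. Of the 9 mural cell genes 1 rose, Tagln (1.55).

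No gene passed limma's test in the lists of myelin (14 genes, 6 at an unadjusted p under 0.05), oligodendrocyte precursors (11, 2), pan-neuronal genes (13, 3), excitatory neurons (12, 2) and inhibitory neurons (11, 2). Nor did any in limma's test for thalamus and hippocampus (10, 3), cerebellum (5, 1), choroid plexus (7, 1), ependyma (9, 2), synapse (15, 4), heat shock (12, 4) and mitochondrially encoded genes (13, 0). Adjusted over the list alone, 1 myelin gene rose and 2 fell, and 3 heat shock genes rose and 1 fell. By the same measure 1 thalamus and hippocampus gene rose, 1 inhibitory neuron gene fell and no gene of the other lists passed. None of the 10 m6A writer genes and none of the 13 eraser and reader genes passed limma's test (0 and 0 at an unadjusted p under 0.05). Over all 13666 tested genes, 2936 had an unadjusted p under 0.05 in limma's test of this comparison. Mettl3, the methyltransferase, had 2.65 ± 0.0701 FPKM in sham and 2.53 ± 0.229 FPKM in ICH.

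In all, 776 genes passed an adjusted p of 0.05 (limma), 677 higher and 99 lower in ICH, of which 365 and 21 changed at least 2-fold. Without sham replicates 1, 2 and 3 the lower genes numbered 24, 47 and 19 and the higher genes 363, 383 and 391. With camera at the preset correlation, 17 of the 34 lists passed, 12 up and 5 down. With an estimated correlation 7 passed: microglia (limma adjusted p = 0.0453), phagocytes (0.0235), reactive astrocytes (0.0472), cytokines (0.0453), complement (0.0235), haem and iron handling (0.0490) and cell cycle (0.0235). Camera's adjusted p with an estimated correlation (limma) was 0.194 for interferon response, 0.146 for matrix, 0.122 for ferroptosis, 0.156 for apoptosis and 0.122 for endothelium. For the lists that were down it was adjusted p = 0.157 with an estimated correlation (limma) for striatal neurons, 0.168 for neuropeptides, 0.436 for immediate early genes, 0.222 for erythroid transcripts and 0.607 for myelin. Without ICH replicate 1 the lists of ferroptosis, apoptosis, erythroid transcripts, myelin, immediate early genes and neuropeptides did not pass camera, and the mean log2 fold change went from -1.06 to -0.68 for erythroid transcripts, from -0.92 to -0.52 for immediate early genes and from -0.49 to -0.28 for neuropeptides. The gene count became 5212 without ICH replicate 1, when ICH replicate 2 stood alone, and 387, 430 and 410 without sham replicates 1, 2 and 3.

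**Figure D2:**
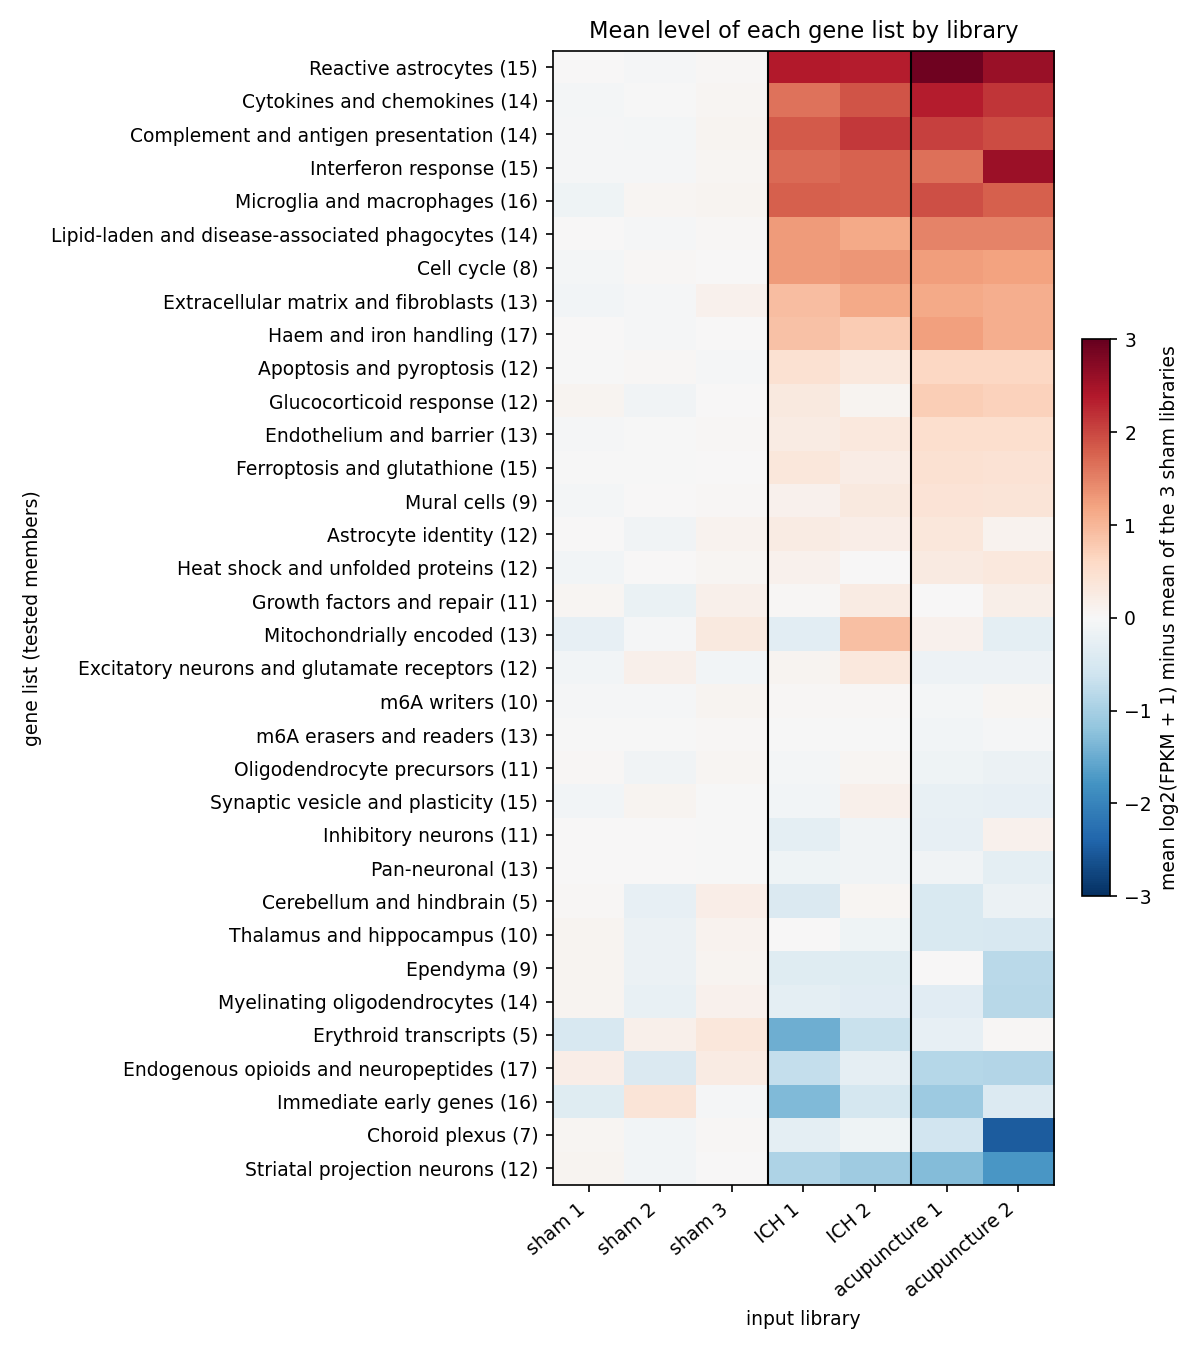
Mean log2(FPKM + 1) of each of the 34 tested gene lists (vertical axis, with its number of tested members) in each input library (horizontal axis), as the difference from the mean of the 3 sham libraries (colour). Reactive astrocyte genes averaged 3.80 and 3.78 in the ICH libraries, and choroid plexus genes 2.27 and 0.36 in the acupuncture libraries.

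The second comparison, acupuncture against ICH, asked what treatment changed in mice with a haemorrhage. Of 13666 genes, 5 passed the test. At an unadjusted p under 0.05 (limma) there were 2754, beside 2936 in ICH against sham, so the 5 calls do not show that the groups were alike. Ctla2a, a cysteine protease inhibitor (ENSMUSG00000044258; GRCm38 chromosome 13, 60934155 to 60936625), rose from 4.703 ± 0.949 FPKM in ICH (SD, n = 2) to 18.2 ± 1.45 FPKM in acupuncture (SD, n = 2), beside 1.31 ± 0.167 FPKM in sham. Its log2 fold change was 1.76 (SE 0.14, limma adjusted p = 0.0176). Saa3, an acute phase protein, had 44.4 ± 25.9 FPKM in ICH and 310.1 ± 19.0 FPKM in acupuncture and did not pass (limma adjusted p = 0.0789). Pde10a, a phosphodiesterase of striatal neurons, had 14.7 ± 1.43 FPKM in ICH and 6.57 ± 0.966 FPKM in acupuncture (limma adjusted p = 0.0789).

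The 5 genes that passed were all higher in acupuncture, and all 5 are uncertain. Ctla2a has a neighbouring paralogue, Ctla2b, that may share its reads; Ctla2b, chosen after its values were seen, had 2.11 ± 0.635 FPKM in ICH and 5.63 ± 0.122 FPKM in acupuncture. Rps12-ps4 (4.23) and Rpl10-ps3 (3.25) are pseudogenes that may share reads with Rps12 and Rpl10. Gm14150 (2.55) is a gene model without an approved symbol, named here after its values were seen. Vps25 (1.64), a subunit of the ESCRT-II complex, went from 7.00 ± 0.155 to 24.1 ± 3.10 FPKM. Ramp2, chosen after its values were seen because it covers Vps25 on the same strand, had 14.0 ± 1.98 FPKM in ICH and 6.63 ± 2.00 FPKM in acupuncture. Among genes that did not pass, log2 fold changes were 1.70 for Fpr1 and 1.49 for Fpr2, receptors for formyl peptides, 1.12 for Hspb1, 1.87 for S100a8, a calcium-binding protein of neutrophils, and 0.84 for Fcgr4. They were -0.96 for Shc3, -1.12 for Xkr4, -0.84 for Hs6st3 and -0.69 for Tshz2, and Klhdc7a was listed at 0 in both acupuncture libraries. These genes passed without ICH replicate 1, when ICH replicate 2 stood alone, and Saa3 without either ICH library.

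Of the 34 lists, 12 passed camera at the preset correlation, 5 up and 7 down, and 0 with an estimated correlation (smallest limma adjusted p = 0.420). The fry test called 7 lists. Of these, haem and iron handling, thalamus and hippocampus and glucocorticoid response were among the 12 of camera. The others, phagocytes, ferroptosis, apoptosis and endothelium, were not, so fry did not call the remaining lists of the 12. No list had a member past the test over all genes. Up were reactive astrocytes (mean log2 fold change 0.39; 5 of 15 higher adjusted over the list alone) and cytokines (0.50; 6 of 14), in which Tnf had 0.947 ± 0.329 FPKM in ICH and 3.30 ± 0.381 FPKM in acupuncture. Also up were glucocorticoid response (0.52; 3 of 12), haem and iron handling (0.34; 3 of 17) and erythroid transcripts (0.96; 1 of 5). Down were striatal neurons (-0.53; 6 of 12 lower adjusted over the list alone), thalamus and hippocampus (-0.41; 4 of 10), excitatory neurons (-0.35; 3 of 12) and synaptic genes (-0.27; 1 of 15). Choroid plexus (-1.32; 4 of 7), myelin (-0.26; 0 of 14) and mitochondrially encoded genes (-0.38; 0 of 13) were down as well. Ttr, a choroid plexus transcript chosen after its values were seen, had 335 FPKM in acupuncture replicate 1 and 1.13 FPKM in acupuncture replicate 2. Without acupuncture replicate 2 the mean of the choroid plexus list was -0.36, that of striatal neurons -0.30 and that of myelin -0.01, and without ICH replicate 2 that of the mitochondrial list was 0.23, that of synaptic genes -0.15 and that of excitatory neurons -0.23. It was 0.22 for reactive astrocytes, -2.27 for choroid plexus, -0.51 for myelin and -0.59 for the mitochondrial list without acupuncture replicate 1, 0.57 for erythroid transcripts and -0.98 for the mitochondrial list without ICH replicate 1, and -0.17 for the mitochondrial list without acupuncture replicate 2. Without ICH replicate 1 the lists of reactive astrocytes, cytokines, glucocorticoid response, haem and iron handling, erythroid transcripts, striatal neurons, thalamus and hippocampus, choroid plexus and myelin did not pass camera. Nor did reactive astrocytes and haem and iron handling without acupuncture replicate 1, erythroid transcripts without either acupuncture library, myelin without acupuncture replicate 2 and the mitochondrial list without ICH replicate 2 or acupuncture replicate 2.

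No m6A writer, eraser or reader gene passed limma's test (0 of 10 and 0 of 13). At an unadjusted p under 0.05 (limma) there were 0 and 2, beside 2754 of all 13666 genes. Mettl3 had 3.001 ± 0.499 FPKM in acupuncture and Fto, a demethylase, 9.22 ± 0.336 FPKM, beside 10.7 ± 0.272 FPKM in ICH. The count of 5 genes became 5105 without ICH replicate 1, 16 without acupuncture replicate 1, 8 without sham replicate 2 and 2 without sham replicate 1 or 3. Ctla2a and Gm14150 did not pass without sham replicate 1 or 3 or either acupuncture library, and Vps25 not without sham replicate 1 or 3, ICH replicate 2 or acupuncture replicate 2.

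Against sham, which asked how far the treated tissue was from tissue without a haemorrhage, the acupuncture libraries showed many of the same groups of genes. Hmox1 rose to 245 ± 6.47 FPKM, a log2 fold change of 6.23 (SE 0.11, limma adjusted p = 2.4e-06; n = 2 against 3). Saa3 rose from 2.72 ± 0.146 to 310.1 ± 19.0 FPKM (6.38, SE 0.32, limma adjusted p = 8.08e-05). The other largest increases were Timp1 (5.46), Serpina3n (5.39), Lcn2 (5.33), Lyz2 (4.78), Ccl12 (4.74), Tgm1 (4.51), Ifi30 (4.17), Cd52 (4.05), Gfap (3.90) and Vim (3.88). Pde10a fell from 24.7 ± 1.12 to 6.57 ± 0.966 FPKM (-1.77, SE 0.12, limma adjusted p = 2.15e-04) and Adora2a, an adenosine receptor, from 20.02 ± 1.495 to 5.72 ± 2.58 FPKM. Shox2 (-2.15), Rgs9 (-1.87), Slc17a6, a vesicular glutamate transporter (-1.74), Nts (-1.72), Unc13c (-1.70), Cartpt (-1.68), Drd2 (-1.67), Lrrc10b (-1.64) and Nexn (-1.62) fell too. Of these, Drd2 did not pass without acupuncture replicate 2, nor did Slc17a6 without either acupuncture library. Cartpt did not pass without sham replicate 1 or either acupuncture library, Nts without sham replicate 1 or 3 or either acupuncture library, and Lrrc10b without any sham or acupuncture library.

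In this comparison 15 of 16 microglia genes rose and 1 fell (15 and 1 adjusted over the list alone), and 15 of 15 reactive astrocyte and 15 of 15 interferon genes rose (15 and 15 adjusted over the list alone). Of cytokines 13 of 14 rose, of complement genes 13 of 14, of phagocyte genes 11 of 14 and of cell cycle genes 8 of 8 (13, 14, 12 and 8 adjusted over the list alone). In haem and iron handling, 9 of 17 rose and 1 fell (10 and 1 adjusted over the list alone). Matrix genes rose in 7 of 13, endothelial genes in 6 of 13, ferroptosis genes in 6 of 15, apoptosis genes in 5 of 12 and glucocorticoid genes in 5 of 12 (10, 6, 8, 6 and 6 higher adjusted over the list alone). Slc2a1, the glucose transporter of brain endothelium, rose from 21.6 ± 1.78 to 42.5 ± 3.18 FPKM (0.95), and Mt2, a metallothionein, from 109 ± 17.4 to 486 ± 56.8 FPKM (2.16).

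The 12 striatal neuron genes all fell (12 adjusted over the list alone). Of the 14 myelin genes, 4 fell and 1 rose (9 and 1 adjusted over the list alone). Of the 10 thalamus and hippocampus genes 4 fell, among them Prkcd (-1.43; not past without acupuncture replicate 2) and Tcf7l2 (-1.60; not past without either acupuncture library), of the 7 choroid plexus genes 2 and of the 17 neuropeptide genes 4 (4, 5 and 8 adjusted over the list alone). The mean log2 fold change of the choroid plexus list was -1.53 and that of myelin -0.58, but -0.58 and -0.33 without acupuncture replicate 2, and it was -2.49 for choroid plexus without acupuncture replicate 1. Of the immediate early genes 2 of 16 fell, and of the synaptic genes 1 of 15, Shank3 (-0.76, not past without acupuncture replicate 2). In limma's tests of pan-neuronal and ependymal genes 0 of 13 and 0 of 9 passed. At an unadjusted p under 0.05 (limma) there were 3 and 2, beside 3486 of all 13666 genes.

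In all, 1598 genes passed (limma), 1158 higher and 440 lower in acupuncture, and after quantile normalization 923 were higher and 721 lower. With camera 22 lists passed, 13 up and 9 down, and 7 with an estimated correlation: microglia (limma adjusted p = 0.0475), phagocytes (0.0343), reactive astrocytes (0.0475), cytokines (0.0466), complement (0.0343), haem and iron handling (0.0466) and cell cycle (0.0343). For the other lists that were up it was adjusted p = 0.170 with an estimated correlation (limma) for interferon response, 0.162 for matrix, 0.0568 for endothelium, 0.0732 for ferroptosis, 0.0732 for apoptosis and 0.109 for glucocorticoid response. For those that were down it was adjusted p = 0.0963 with an estimated correlation (limma) for striatal neurons, 0.0963 for neuropeptides, 0.295 for myelin, 0.217 for thalamus and hippocampus and 0.247 for choroid plexus. It was adjusted p = 0.335 with an estimated correlation (limma) for immediate early genes, 0.170 for synaptic genes, 0.167 for pan-neuronal genes and 0.466 for ependyma. The lists of pan-neuronal genes and of thalamus and hippocampus did not pass camera without acupuncture replicate 2, nor did ependyma without sham replicate 1, either ICH library or acupuncture replicate 2. Without acupuncture replicate 2 the mean log2 fold change went from -0.20 to -0.11 for pan-neuronal genes and from -0.40 to 0.009 for ependyma, and without acupuncture replicate 1 to -0.81 for ependyma and from -0.75 to -0.40 for immediate early genes. The gene count became 3215 and 3209 without ICH replicates 1 and 2, 840, 1045 and 873 without sham replicates 1, 2 and 3, and 809 and 805 without acupuncture replicates 1 and 2.

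When the 4 haemorrhage libraries were joined, 1123 genes passed against sham (limma), 917 higher and 206 lower. Gfap averaged 386 ± 48.9 FPKM (SD, n = 4) against 26.2 ± 2.79 FPKM (SD, n = 3), a log2 fold change of 3.83 (SE 0.13, limma adjusted p = 1.29e-05). Penk averaged 74.2 ± 8.79 FPKM (-1.26, SE 0.12, limma adjusted p = 5.96e-04), and Scn4b, a sodium channel subunit of striatal neurons, 26.2 ± 9.30 FPKM (-1.34, limma adjusted p = 0.0153), though it did not pass without any 1 of the sham libraries. Of the striatal neuron genes 11 of 12 fell (12 adjusted over the list alone), and of the interferon genes 15 of 15 rose (15 adjusted over the list alone). With camera 18 lists passed, and 3 with an estimated correlation: microglia, complement and cell cycle. The count became 2162 without ICH replicate 2 and 578, 670 and 605 without sham replicates 1, 2 and 3.

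Most genes raised by haemorrhage were further from sham in the acupuncture libraries than in the ICH libraries. Of the 677 genes raised in ICH, 483 (71.3%) had a higher mean in acupuncture and 194 a lower one; of the 99 that fell, 51 were further from sham and 48 closer. Against ICH replicate 1 alone 81.1% of the raised genes were further from sham, and against ICH replicate 2 alone 61.0%. C3 was closer to sham at 10.4 ± 5.25 FPKM in acupuncture, and Timp1 at 60.9 ± 21.1 FPKM was further away than in ICH, at 29.9 ± 3.47 FPKM. In simulated data without a difference between ICH and acupuncture the share was 40.4% (37.9% to 42.5%), because raised genes were chosen on the ICH libraries. This comparison was chosen after the share was seen. Simulated genes varied independently, with the same spread in all libraries, so shifts of many genes together in a library are left out. The simulated range may therefore be too narrow. Between 2 libraries of 1 group, up to 65.9% of these genes were higher in 1 of them (acupuncture replicate 1 over 2). The difference itself passed the test for 1 of the 677, Ctla2a, and for 2 of the 99, Vps25 and Rps12-ps4.

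Of the genes called against sham, 626 were higher and 66 lower in both ICH and acupuncture, and 1, Rps12-ps4, was lower in ICH and higher in acupuncture. Independent lists would share 57.4 and 3.2, and simulated lists that share only the sham libraries 260 in both directions together. Fold changes of acupuncture against ICH and of ICH against sham had a covariance of -0.0370 across genes, beside -0.0205 simulated for unchanged groups that share the ICH libraries. The Pearson correlation of the same pair was -0.230, smaller in size than the -0.546 simulated. Without ICH replicate 2 the covariance was 0.00132. The simulation gave all libraries the same spread per gene and no effect of the haemorrhage. The ICH libraries differed by a median of 0.266 on the log2 scale, beside 0.126 for acupuncture and 0.080 to 0.103 for sham. The simulated covariance may therefore be too small in size, and these values do not show a return towards sham. Fold changes of acupuncture and of ICH against sham, which share the sham libraries, had a covariance of 0.158, beside 0.0138 simulated, and a Pearson correlation of 0.710, beside 0.401 simulated; genes are not independent replicates.

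The authors listed 48251 m6A peaks in sham, 54754 in ICH and 50105 in acupuncture, from 1 list per group without replicates. The sources used here do not say which libraries entered the peak lists and the tables of differential peaks, so the libraries behind the ICH and acupuncture peaks may differ from those of the input values. Peaks were found in transcripts of 17083, 17511 and 17435 genes, and 15909 genes had a peak in all 3 lists. Among the 13666 genes tested for expression, 93.6%, 94.3% and 94.0% had a peak. Most peaks lay in the 3' UTR, which held 54.5% of the sham peaks, 52.3% of the ICH peaks (95% Wilson interval 51.9 to 52.7) and 54.7% of the acupuncture peaks (54.3 to 55.2). Coding or other exons held 20.1%, 21.8% and 20.4%, and the 5' UTR 11.6%, 12.1% and 11.2%. Non-coding RNA exons held 8.8%, 8.2% and 8.4%, and introns 4.6%, 5.3% and 5.0%. The intervals cover counting error alone. The median span was 525, 575 and 536 bp; spans run from the first to the last base of a peak with introns included, and 38.5%, 39.0% and 37.9% exceeded 1000 bp.

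Most peaks of 1 group overlapped a peak of another group by at least 1 bp on the same strand. Of the sham peaks, 80.2% overlapped an ICH peak and 76.6% an acupuncture peak. Of the ICH peaks, 71.0% overlapped a sham peak and 74.6% an acupuncture peak, and of the acupuncture peaks 75.05% and 82.6% overlapped sham and ICH peaks.

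In the authors' deposited table of ICH against sham, most differential peaks were higher in ICH. The authors' deposited table held 23112 peaks, 18184 (78.7%) higher and 4928 lower in ICH. Rpl30, a ribosomal protein transcript, carried the largest increase among the peaks named from the authors' deposited table, in its 3' UTR (GRCm38 chromosome 15, 34440505 to 34440854). Its log2 IP over input was 7.59 and 0.91 in ICH and sham in the authors' deposited table (adjusted p = 2.67e-50 as the authors gave it). Gbp3, an interferon-induced GTPase, carried a higher peak in its 5' UTR in ICH (chromosome 3, 142560503 to 142560602; 2.13 and -2.43 in the authors' deposited table). The Gbp3 value is uncertain, as its input had 1.19 FPKM in sham and 5.55 FPKM in ICH. Lower in ICH in the authors' deposited table were a 5' UTR peak of Jag2, a Notch ligand (chromosome 12, 112929437 to 112929536; -0.96 and 3.31), and an exon peak of Mki67, a proliferation marker (chromosome 7, 135707707 to 135708131; 2.19 and 5.33). The Mki67 value is uncertain, as its input had 0.197 FPKM in sham and 3.32 FPKM in ICH.

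In the authors' deposited table of acupuncture against ICH, the direction was the opposite. The authors' deposited table held 20899 peaks, 3897 (18.6%) higher and 17002 lower in acupuncture. The Rpl30 3' UTR peak was lower in acupuncture (chromosome 15, 34440505 to 34440779; 2.10 and 8.04 in acupuncture and ICH in the authors' deposited table). A peak in the pseudogene Pabpc1l2a-ps had -5.22 and 6.76 in acupuncture and ICH in the authors' deposited table (chromosome X, 103066668 to 103067167), and its reads may be shared with a near-identical gene. Pebp1, a regulator of Raf kinase, carried an exon peak that was higher in acupuncture (chromosome 5, 117284623 to 117285943; 4.92 and -0.46 in the authors' deposited table). An intronic peak of Uvrag, an autophagy gene, was higher as well (chromosome 7, 98905713 to 98906212; 7.38 and 2.63 in the authors' deposited table).

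The authors' deposited table of acupuncture against sham held 17180 peaks, 10009 (58.3%) higher and 7171 lower in acupuncture. An exon peak of Pebp1 was higher in acupuncture than in sham too (chromosome 5, 117285769 to 117285943; 4.93 and -1.08 in the authors' deposited table). An exon peak of Slit2, an axon guidance ligand, was lower (chromosome 5, 48230319 to 48231623; -4.07 and 0.90 in the authors' deposited table), on an input of 1.22 FPKM in sham and 0.720 FPKM in acupuncture. Zbp1, a nucleic acid sensor, carried a 3' UTR peak that was lower in acupuncture (chromosome 2, 173206612 to 173207211; 0.99 and 4.91 in the authors' deposited table), which is uncertain because its input had 0.0582 FPKM in sham and 1.91 FPKM in acupuncture.

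**Figure D3:**
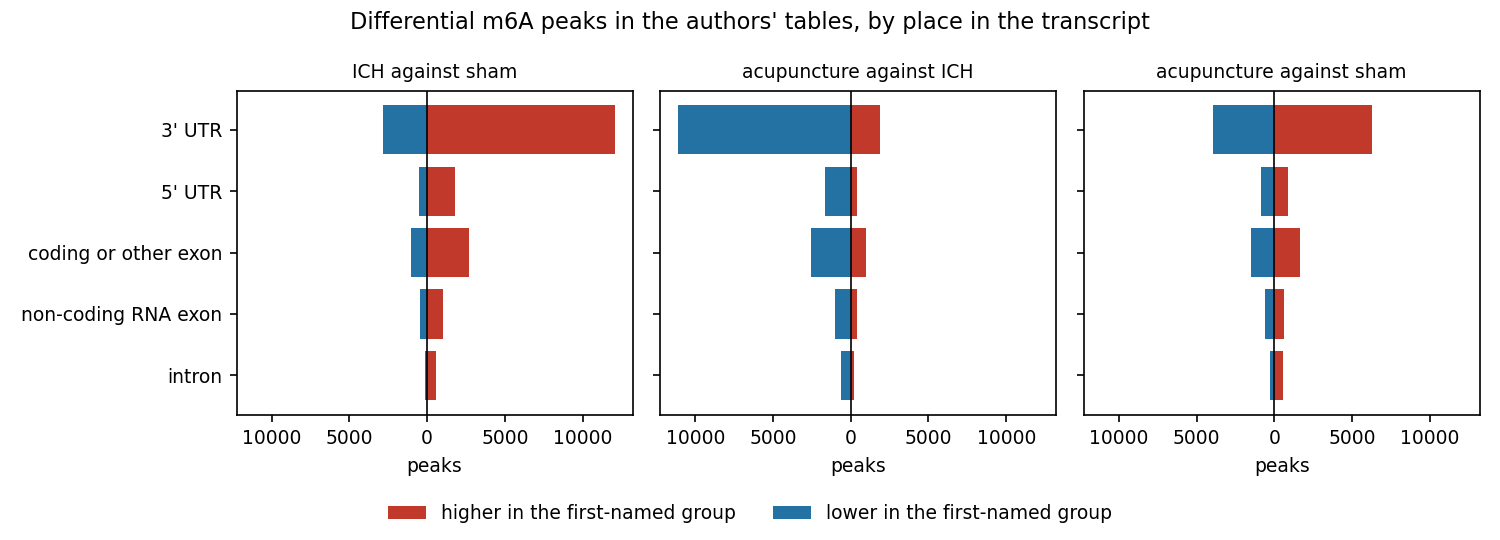
Number of peaks (horizontal axes) in the authors' deposited tables that were higher (right, red) or lower (left, blue) in the first-named group, by place in the transcript (vertical axis), for the 3 comparisons. In the 3' UTR of the authors' deposited tables, 12057 of 14888 peaks were higher in ICH than in sham and 1904 of 13005 were higher in acupuncture than in ICH.

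The shift was present in each place of the transcript. In the authors' deposited table of ICH against sham, 81.0% of 3' UTR, 77.5% of 5' UTR, 72.4% of exon, 70.5% of non-coding RNA and 84.2% of intron peaks were higher in ICH. In the authors' deposited table of acupuncture against ICH, 14.6%, 19.7%, 27.7%, 27.9% and 23.9% were higher in acupuncture. Of the peaks higher in ICH than in sham, 3234 had identical borders in both of the authors' deposited tables, and 3227 of these (99.8%) were lower in acupuncture than in ICH. Lower peaks made up 81.4% of the second of the authors' deposited tables. Both tables share the ICH group and list peaks selected by p-value, which favours opposite directions. The share to be found without a change was not simulated. Of the peaks lower in ICH than in sham, 257 had identical borders in both of the authors' deposited tables, and 241 of these (93.8%) were higher in acupuncture than in ICH, beside 18.6% of all peaks of the second table. With at least a 2-fold difference the authors' deposited tables held 5156, 4212 and 4136 peaks, of which 80.4% were higher in ICH than in sham and 29.8% higher in acupuncture than in ICH.

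Peaks were also counted per gene list. Of 13656 tested genes, 7358 had higher peaks alone and 1206 lower peaks alone in ICH in the authors' deposited table, and 964 and 7488 in acupuncture against ICH. Of the 10 m6A writer genes, 5 had higher peaks alone, 0 lower peaks alone, 3 both and 2 neither in ICH in the authors' deposited table, and 1, 6, 1 and 2 in acupuncture against ICH. Of the 17 haem and iron handling genes, 14 had higher peaks alone in ICH in the authors' deposited table, and 11 lower peaks alone in acupuncture against ICH. Of the 16 microglia genes, 12 had higher peaks alone in ICH and 11 lower peaks alone in acupuncture against ICH in the authors' deposited tables. The cell cycle list had 2 genes with higher and 3 with lower peaks alone of 8 in ICH in the authors' deposited table, the interferon list 6 and 5 of 15, the cerebellum list 2 and 2 of 5 and the mitochondrially encoded list 1 and 4 of 13.

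Of the 776 genes called in the input between ICH and sham, 505 (65.1%) had a peak in the authors' deposited table, beside 77.8% of all tested genes. Among these, 315 were higher in both RNA and m6A, 109 higher in RNA with lower m6A, 73 lower in RNA with higher m6A and 8 lower in both, with m6A from the authors' deposited table. Of the genes that were not called and had a differential peak, 83.3% had higher m6A in ICH in the authors' deposited table, beside 74.3% of those called higher and 90.1% of those called lower. Across genes, RNA and m6A differences had a Spearman correlation of -0.236 in this comparison, and genes are not independent replicates. It was -0.219 in acupuncture against ICH and -0.051 in acupuncture against sham. The input is also the denominator of IP over input. A negative correlation and the order of these shares can therefore arise without a change of m6A. Between acupuncture and sham, 913 called genes had a peak in the authors' deposited table, 303 higher in both, 288 higher in RNA with lower m6A, 213 lower in RNA with higher m6A and 109 lower in both.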

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

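Quantities were compared among the 4 haemorrhage libraries, which the further fit joins although they come from 2 groups, and 5 of 38 had a library far from the other 3 by Dixon's ratio of the gap to the range. Chance passes this limit in about 1 of 20 groups of 4 libraries from 1 population, which these are not, so this rate is only a guide here. The myelin list was lowest in acupuncture replicate 2, at 5.19 on the log2 scale, against 5.68 to 5.72 in the other 3 (ratio 0.926). The pan-neuronal list was lowest in the same library, at 6.30 against 6.47 to 6.50 (ratio 0.874), and the interferon list highest, at 4.04 against 3.12 to 3.24 (ratio 0.866). The microglia list was highest in acupuncture replicate 1, at 5.38 against 5.23 to 5.25 (ratio 0.857). ICH replicate 2 had the fewest genes above 0, 23495 against 24550 to 24746 (ratio 0.843). No explanation of these values was tested.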

How the results depend on the processing

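Removal of the gene span trend, the 1000 bp span limit and all alternatives of the direction share were chosen after the result was seen. Named genes gave 4799 values under the alternatives. Of these 4351 kept their direction and side of the threshold, 431 kept the direction but were no longer past it, 17 newly passed and 0 reversed. For called lists the numbers were 540, 70, 0 and 2 of 612. Gene counts stayed within 1.5 times under the other pseudocounts, rescalings, variance models and filter on any value above 0. The genes called were not all the same. With the filter on any value above 0, 454 of the 776 genes were called again in ICH against sham. The numbers were 2 of 5 in acupuncture against ICH, 1105 of 1598 in acupuncture against sham and 805 of 1123 for both haemorrhage groups. The cause was not tested except where stated.

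With a filter at 5 FPKM, which tests fewer genes, 250 genes passed in ICH against sham, 707 in acupuncture against sham and 383 for both haemorrhage groups. With the replicate block the counts were 351, 3 (acupuncture against ICH), 750 and 463, although the replicate numbers did not pair libraries. A fit of only the 2 groups compared gave 2 in acupuncture against ICH and 3207 in acupuncture against sham. With an estimated correlation 7, 0 and 7 lists passed. Leaving out 1 library, where a lone sample is assumed to vary like the other groups, gave 387 to 5212 genes in ICH against sham, 2 to 5105 in acupuncture against ICH, 805 to 3215 in acupuncture against sham and 578 to 2162 for both groups. It gave 3 to 16 lists in acupuncture against ICH. The mean of the mitochondrial list in acupuncture against ICH ranged from -0.98 to 0.23 and reversed without ICH replicate 2. That of the ependymal list in acupuncture against sham ranged from -0.81 to 0.009 and reversed without acupuncture replicate 2.

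The covariance of acupuncture against ICH with ICH against sham was -0.0608 with a pseudocount of 0.1, -0.0430 with the filter at 5 FPKM, -0.0402 after quantile normalization and -0.0331 with the gene span trend removed. It ranged from -0.189 to 0.00132 when 1 library was left out, and reversed without ICH replicate 2. The share of raised genes further from sham was 77.7% at 5 FPKM, 63.5% after quantile normalization, 63.7% with the trend removed and 61.0% to 81.1% with 1 library left out.

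Peaks of at least 4-fold enrichment numbered 7492 in sham, 10627 in ICH and 7501 in acupuncture. Overlap shares follow in the order sham in ICH, sham in acupuncture, ICH in sham, ICH in acupuncture, acupuncture in sham and acupuncture in ICH. With an overlap of at least 0.5 of both peaks they were 53.01%, 54.51%, 46.71%, 52.65%, 52.49% and 57.54%. On either strand they were 81.23%, 77.65%, 72.06%, 75.55%, 76.09% and 83.42%. Among peaks of at least 4-fold enrichment they were 79.74%, 76.11%, 56.69%, 58.27%, 76.91% and 82.52%. Among peaks spanning at most 1000 bp they were 61.28%, 61.31%, 53.73%, 59.64%, 58.12% and 64.46%. In the authors' deposited tables a 2-fold minimum left 5156, 4212 and 4136 differential peaks, and in acupuncture against sham an FDR under 0.05 left 10974 and a p under 0.01 left 10858. FPKM gives no depth, so what depth limits could not be assessed. The IP-to-input test per gene and its alternatives were not run, because the FPKM table used here has no IP columns.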

Other observations

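Of the 11 growth factor genes, 8 did not pass in ICH against sham. Tgfb1 rose from 0.793 ± 0.0723 FPKM in sham (SD, n = 3) to 4.40 ± 1.94 FPKM in ICH (SD, n = 2; log2 fold change 1.54), and Fgf2 from 0.734 ± 0.0740 to 2.22 ± 0.350 FPKM (0.89). Vegfa fell from 14.8 ± 1.71 to 7.92 ± 0.147 FPKM (-0.82) and had 7.75 ± 1.45 FPKM in acupuncture; it did not pass without sham replicate 2 or 3 or ICH replicate 2. Of the glucocorticoid response genes, Mt1 rose from 92.2 ± 12.2 to 271 ± 109.6 FPKM and Per1, a clock gene, fell by 0.65 on the log2 scale. Neither passed without any 1 of the sham libraries, and Per1 not without either acupuncture library. Of the 12 heat shock genes, 3 rose in acupuncture against sham (4 adjusted over the list alone), with Hspb1 at 3.75 ± 0.194 FPKM in sham and 14.2 ± 0.549 FPKM in acupuncture (1.67).

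In lists too small to test, the neutrophil genes S100a8 and S100a9 rose in acupuncture against sham, from 3.08 ± 0.531 to 25.0 ± 8.29 FPKM and from 5.21 ± 1.12 to 35.6 ± 11.1 FPKM. Cd4 fell from 3.86 ± 0.317 to 1.07 ± 0.217 FPKM (-1.24). Among sex-linked genes Ddx3y had a log2 fold change of -0.35 in acupuncture against sham, which did not pass without any 1 sham or acupuncture library, and Kdm5d, Uty and Eif2s3y did not pass.

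All tests below except that of the splits were chosen after the result was seen. For both haemorrhage groups against sham, 1 of the 35 splits of the 7 input libraries into 4 and 3 gave as many genes as the 1123 observed. It was the real split. This is the strongest result that 35 splits allow, so it argues against chance without excluding it. The highest other split, which set ICH replicate 2 with the sham libraries, gave 129.

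Fold changes of acupuncture against ICH followed the span of the gene on the genome, with a Spearman correlation of -0.398 across genes. The median log2 fold change was 0.22 among genes of the shortest span and -0.22 among those of the longest. The ICH replicate 2 library alone is argued against, since the correlation was -0.365 against ICH replicate 1, larger in size than any within a group (0.226 at most). A difference between batches of libraries that follows the group may be the cause, since the correlation was -0.267 against sham. It cannot be told apart from a change of the tissue, because each group has its own libraries.

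Most genes raised in ICH lay further from sham in acupuncture (71.3%). The share was 40.4% when simulated with independent genes and without a difference, and at most 65.9% between 2 libraries of 1 group. ICH replicate 2 alone is argued against, since the share was 81.1% against ICH replicate 1. ICH replicate 1 alone is not excluded, since the share was 61.0% against ICH replicate 2, within the 65.9% found between 2 libraries of 1 group. After quantile normalization the share was 63.5%. The gene span trend may be a cause: with the trend removed the share was 63.7%, within the 66.8% found between 2 libraries of 1 group, so it cannot be told apart from a difference between the groups. A larger share of lesioned tissue in the acupuncture samples was neither shown nor excluded. Striatal neuron genes, which it would lower, had a mean log2 fold change of -0.53 against ICH, though this was -0.30 without acupuncture replicate 2 and the list did not pass with an estimated correlation (limma adjusted p = 0.420). Lists that rose in ICH, which it would raise, had means against ICH of 0.50 for cytokines, 0.39 for reactive astrocytes, 0.37 for interferon response, 0.34 for haem and iron handling, 0.28 for phagocytes, 0.24 for apoptosis, 0.21 for endothelium, 0.17 for ferroptosis and 0.08 for matrix, but 0.07 for microglia, 0.04 for complement and -0.08 for cell cycle, lists that had 1.79, 1.97 and 1.302 in ICH against sham. It cannot be told apart from a changed injury response with 2 libraries per group, and an effect of treatment stays open, as untested. Whether all samples held the same parts of the brain was not tested either. The choroid plexus list averaged 2.27 in acupuncture replicate 1 and 0.36 in acupuncture replicate 2.

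Differential peaks in the authors' deposited tables were mostly higher in ICH than in sham and mostly lower in acupuncture than in ICH. The authors gave these values per group only. Whether an individual library, such as ICH replicate 2, gave this pattern could therefore not be tested. Changed input levels of the same genes are argued against as the whole cause. Of genes with a differential peak, higher m6A in ICH was found in 83.3% of those not called in the input and in 74.3% of those with a raised input in the authors' deposited table. They may be a part of the cause, as the share was 90.1% among genes with a lowered input. The gene span trend of the input is argued against as the whole cause as well, since the share of peaks higher in ICH than in sham was at least 70.1% in each of 4 groups of gene span. The trend may be a part of the cause. This share fell from 82.6% in the group of shortest span to 70.1% in that of longest span. In acupuncture against ICH the share of higher peaks rose from 14.9% to 25.2% between these groups. A more efficient immunoprecipitation in ICH may be the cause, since at least 70.5% of peaks were higher in every place in the transcript. It cannot be told apart from a rise of m6A in all transcripts, because both raise IP over input alike and no measure of total m6A was used here.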
